A study of Wollemia nobilis with 2 samples.

How the data were processed

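Bisulfite sequencing libraries were made from genomic DNA of Wollemia nobilis, 1 from ovules and 1 from mature pollen. Per the labels' protocols, DNA was isolated with a CTAB buffer, converted with a Zymo Research Methylation-Gold kit, made into libraries with a NEXTFLEX Bisulfite-Seq kit and sequenced in paired ends on a NextSeq. Bismark version 0.23.1, which aligns bisulfite reads and calls methylation, and deepTools are named in the submitters' processing notes, without the role each had. The genome build, gene annotation, coverage minimum and any removal of duplicate reads were not given in the sources used here.

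The authors deposited 6 lists of positions, 1 per library and context. Per the deposited files, each has 3 columns, the sequence name and the start and end of a run of adjacent cytosine positions, and other values such as methylation levels, read counts, coverage, strand or gene names were not used here because these lists do not hold them. Their names state an intersection with genes. No list held repeated intervals, and no 2 intervals of a list touched or overlapped. On the 22 scaffolds found in all 6 lists, no position fell into more than 1 context. Other sequences were not checked for this. Each interval was expanded to single cytosines. The ovule lists began later in the order of sequences than the pollen lists, so comparisons between libraries used the 22 scaffolds found in all 6 lists. Organelle sequences and contigs were described in pollen alone. Positions are printed counted from 1.

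The analyses fixed before the data were examined were the methylation level per context and gene, Fisher's exact tests per cytosine, a profile along genes, context classes of genes and gene lists by name. They need methylated and total calls or gene names and were not run. The analyses reported were chosen after the content of the lists was known. The rule fixed for named genes (the 2 largest changes each way where only identifiers are known, with a 95% interval from resampling that excludes 0) was applied to blocks, of at least 300 cytosines, with 200-bp segments resampled. The 2 lowest and 2 highest CG ratios were named likewise by rank of the mean of both libraries, whatever their interval.

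To find what listing meant, CG dinucleotides were taken from runs of even length in the union of both CG lists. In such a run the first cytosine of each pair lies on the forward strand and the second on the reverse strand. Listing of each strand (yes or no) was correlated between neighbouring dinucleotides and between the strands of 1 dinucleotide. Because a dinucleotide enters only if each of its cytosines is in 1 or both lists, these correlations hold given that condition. Blocks were cut from the union of all lists at gaps of over 1000 bp. Intervals are 95% percentile intervals from 1000 resamplings of blocks (or of 200-bp segments within a block, or 200 resamplings for the matched comparison of edges), with a fixed seed. They cover the choice of blocks and patchy coverage within the 2 libraries. They do not cover differences between plants or preparations, and no p-value was computed. Wilson intervals cover counting error only. Read depth was unknown, and the share of CG cytosines whose opposite strand was also listed served as a measure of how fully a sequence was covered. Windows of 1000 bp entered with at least 200 listed cytosines, counted over both libraries for the comparison of recovery. The comparison of CG with CHH recovery in the same windows used every window with both contexts listed, weighted by its CG cytosines.

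The CG ratio and the strand correlations were tested on simulated data, 20 random sequences with no loss of CG and 20 in which 0.6 of the CG dinucleotides were kept, covered by random fragments on each strand. The mean true ratios of 0.997 and 0.646 were recovered as 0.997 and 0.646, with errors of at most 0.00563 and 0.00787, and the intervals held the true ratio in 20 of 20 sequences in each set. Listing correlated with a mean r of 0.900 and 0.898 on the same strand and of 0.00581 and 9.1e-05 on opposite strands. The fragments were placed on each strand independently, so these correlations were built in, and no other meaning of listing was simulated. The simulated sequences had the same composition throughout and were cut into blocks of equal length. How well the intervals cover the uneven blocks of these data was therefore not tested. Alternatives were other gaps that end a block (500 and 5000 bp), other minimums of cytosines per block (100 and 1000), leaving out scaffold_690, scaffold_8387 or scaffold_9393 in turn, cytosines listed in both libraries only, the median over blocks, only blocks of at least 64000 bp for the edges, with 2000 to 4000 bp or with each of 10 narrower or wider inner distances, and all sequences in both lists of a context. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.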

Results

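Genomic DNA of ovules and of mature pollen from the Wollemi pine (Wollemia nobilis), a conifer of the family Araucariaceae, was converted with bisulfite and sequenced. Bisulfite turns unmethylated cytosines into uracil and leaves methylated cytosines as they are. There was 1 library per tissue, so no difference between tissues had a replicate check. The series profiled methylation in the 2 tissues, but the files analysed here hold positions of cytosines within genes, split by sequence context (CG, CHG and CHH, where H is A, C or T), without methylation levels. Methylation levels of ovule and pollen were therefore not analysed here, and the comparisons concern which genic cytosines were listed in each tissue and the contexts they lay in. The ovule lists held 660208 CG, 714311 CHG and 3093669 CHH cytosines. The pollen lists held 699877 CG, 939499 CHG and 4385272 CHH cytosines. The lists did not span the same sequences, so these totals are not comparable. All pollen lists covered 63 sequences, 54 of them nuclear scaffolds or contigs, 8 mitochondrial and 1 plastid. The ovule CG list covered 48 of them and began at contig_562, the CHG list covered 30 and began at contig_942, and the CHH list covered 22 and began at scaffold_690. Each ovule list thus starts at a different point, and whether its beginning is missing from the deposited files is not known. Ovule and pollen were compared on the 22 scaffolds present in all 6 lists. Read depth per cytosine was unknown.

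The first question was what being listed meant. Listing followed the strand of the DNA, not the CG dinucleotide. On the shared scaffolds, the cytosines of 2 neighbouring CG dinucleotides 2 to 4 bp apart were listed together on the same strand, with a correlation across 26119 pairs of 0.957 in ovule and 0.954 in pollen. The correlation fell with distance, to 0.711 and 0.694 at 30 to 59 bp, and to 0.077 and 0.063 at 200 to 499 bp. The 2 cytosines of 1 CG dinucleotide, which lie on opposite strands, were listed almost independently, with a correlation of 0.015 in ovule and 0.022 in pollen over 240368 dinucleotides. These correlations hold for dinucleotides with each cytosine listed in at least 1 library. Each list was read as the cytosines that sequenced fragments had reached on each strand, which the labels do not state. Other meanings, such as a list of methylated calls only, were not tested.

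**Figure D1:**
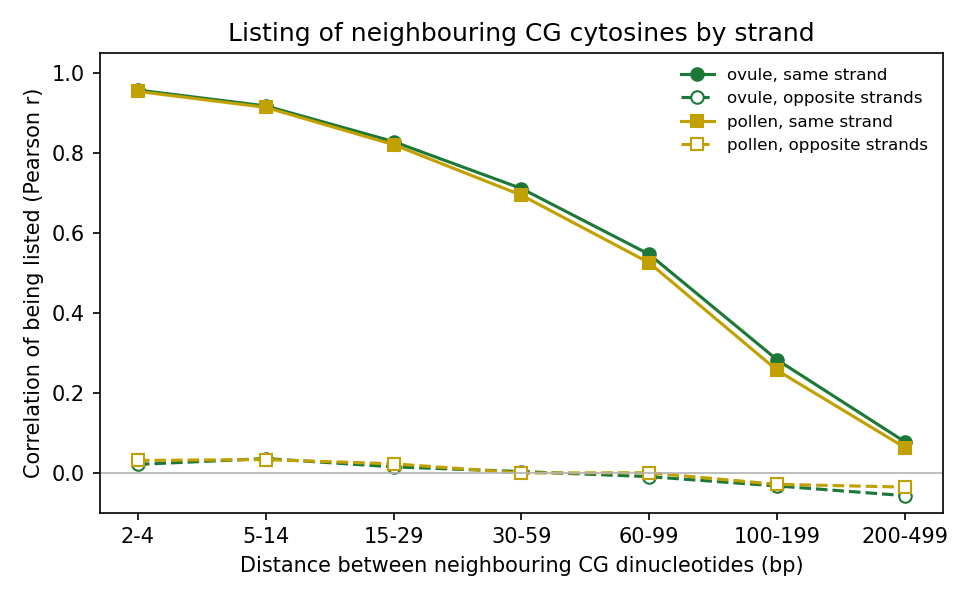
Pearson correlation (vertical axis) between the listing of neighbouring CG cytosines in classes of their distance in bp (horizontal axis), on the same strand (filled symbols) or on opposite strands (open symbols), in ovule and pollen. Same-strand correlations run from 0.957 in ovule at 2 to 4 bp to 0.077 at 200 to 499 bp, while opposite-strand values stay near 0.

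Ovule and pollen were then compared for the genic cytosines they covered. Pollen listed slightly more cytosines than ovule in each context. The pollen to ovule ratio was 1.024 for CG (501080 against 489217 cytosines), 1.023 for CHG (678710 against 663543) and 1.024 for CHH (3169335 against 3093669). The 95% intervals from resampling 838 blocks of listed sequence were 1.0195 to 1.0290 for CG, 1.0182 to 1.0271 for CHG and 1.0195 to 1.0289 for CHH. Pollen listed more than ovule on 21 of the 22 scaffolds, with ratios up to 1.049, and less on scaffold_9198, with a ratio of 0.995. These intervals describe the 2 libraries only, since with 1 library per tissue the spread between plants or preparations was not measured.

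The same cytosines were often covered in both tissues, and CG cytosines more often than CHH cytosines. Of the ovule cytosines, 82.2% of CG (95% interval 81.4% to 83.0%), 79.9% of CHG (79.1% to 80.8%) and 73.7% of CHH (73.0% to 74.5%) were also listed in pollen. The intervals from resampling blocks were wider than binomial ones, for which the Wilson interval for CG was 82.1% to 82.3%. In the other direction, ovule held 80.2% of the pollen CG, 78.2% of the CHG and 72.0% of the CHH cytosines. Recovery rose with the CG content of the sequence. Among 1000-bp windows split into 5 equal classes by CG share, the class poorest in CG (3.09% of listed cytosines) had lower recovery than the richest (21.3%). In the poorest class pollen held 69.2% of ovule CG, 71.4% of ovule CHG and 66.4% of ovule CHH cytosines. In the richest class it held 86.2%, 85.8% and 82.5%. Within these classes CHH recovery was thus the lowest, and CG recovery was not always above that of CHG. The richest class also held more listed cytosines of each context, so CG content was not separated from how fully windows were listed. The pollen to ovule ratio was 1.004 for CG, 1.021 for CHG and 1.028 for CHH cytosines in the poorest class and 1.035, 1.038 and 1.038 in the richest, and it did not rise from class to class throughout in any context.

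Most genic blocks were covered to a similar extent in both tissues. A block was a stretch of cytosines listed in either library without a gap of over 1000 bp. The median block was 3822 bp long and the longest 717063 bp. Among the 574 blocks with at least 300 cytosines, which held 99.4% of all, the median log2 ratio of pollen to ovule was 0.03, and 90% of the blocks lay between -0.34 and 0.37. Pollen was at least 1.5-fold higher in 14 blocks and at least 1.5-fold lower in 10. None of the 574 was listed in 1 library alone, and the longest of the 28 smaller blocks seen in 1 library alone was 429 bp.

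Among blocks with an interval on 1 side of a ratio of 1, the 2 with the highest ratios and the 2 with the lowest are given. Their intervals exclude 1 by that choice and are no added support. Positions are counted from 1 in the sequences as the files name them. The files pair no gene names with these positions. The block at 8798366 to 8804610 of scaffold_9393 held 1075 cytosines in ovule and 2264 in pollen, a ratio of 2.11 (95% interval from resampling 200-bp segments 1.59 to 3.25). The block at 5363617 to 5364860 of scaffold_9647 held 210 in ovule and 436 in pollen, a ratio of 2.08 (1.31 to 3.50). The block at 6822069 to 6823898 of scaffold_9198 held 707 in ovule and 248 in pollen, a ratio of 0.351 (0.150 to 0.714). The block at 4610905 to 4612008 of scaffold_9744 held 366 in ovule and 182 in pollen, a ratio of 0.497 (0.338 to 0.735). The blocks of scaffold_9647 and scaffold_9744 were only 1244 and 1104 bp long, so few segments were resampled in each. The number of blocks past 1.5-fold fell as larger blocks were required, to 2 higher and 1 lower in pollen among blocks with at least 1000 cytosines.

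**Figure D2:**
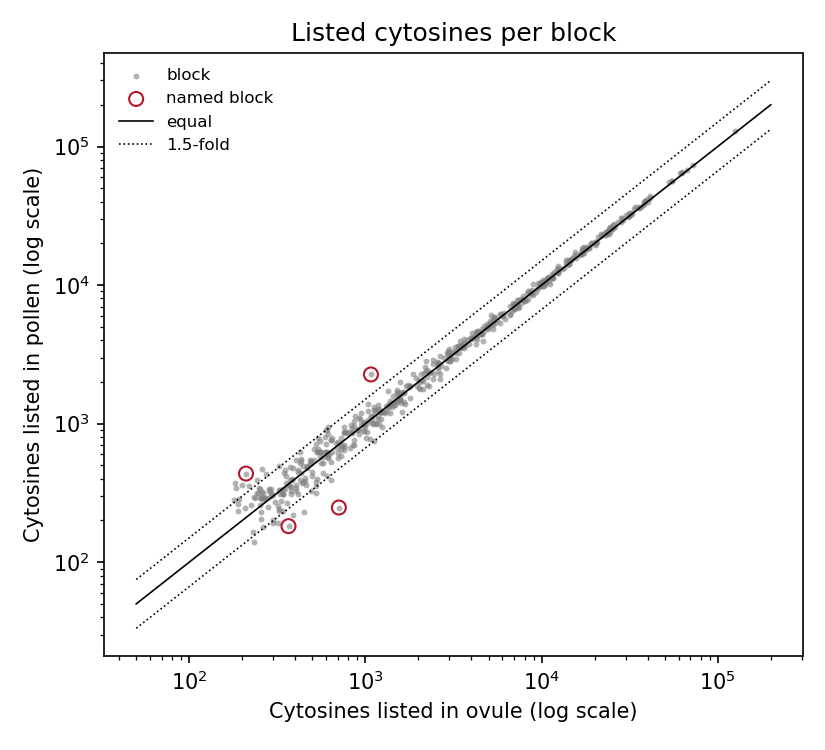
Cytosines listed in pollen (vertical axis, log scale) against ovule (horizontal axis, log scale) for the 574 blocks with at least 300 cytosines, with lines at equality and at 1.5-fold. Of these, 24 lie on or outside the 1.5-fold lines, and the 4 named blocks are circled.

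The contexts of the covered cytosines differed between the 2 libraries by less than resampling of blocks could resolve. The libraries share the reference sequence, and 75.7% of the ovule cytosines were also listed in pollen. Like shares and like ratios are therefore to be expected and say little about the tissues. CG made up 11.5% of the listed cytosines in ovule and in pollen, CHG 15.6% and 15.6%, and CHH 72.9% and 72.9%. The pollen minus ovule difference in CG share was 0.00073 percentage points (95% interval -0.0344 to 0.0367). To set CG against the base composition of the same sequence, a CG ratio was formed. It divides the share of cytosines in CG by the share of the remaining cytosines in CHG, and is 1 where G is as frequent directly after C as 1 base further on. With listing read as coverage, the ratio describes which genic sequence was covered and not its methylation. That reading was not tested against other meanings of listing. The CG ratio was 0.652 in ovule (95% interval 0.639 to 0.664) and 0.653 in pollen (0.640 to 0.665). The difference between the libraries was 0.000882 (-0.000695 to 0.00266).

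Mitochondrial sequences differed from nuclear sequences in this ratio in pollen. The deposited ovule lists start after the organelle sequences in the order of the pollen lists, so their absence there is no measure of the ovule library. Within the pollen library, the 23 scaffolds had a CG ratio of 0.653 (0.642 to 0.664) and the 31 contigs one of 0.666 (0.649 to 0.682). The 8 mitochondrial sequences, with 26942 listed cytosines in 64 blocks, had a ratio of 0.991 (0.934 to 1.11), above the nuclear intervals. The mitochondrial sequence Mt_3 had 1.07 (1.002 to 1.141) and Mt_4 had 0.953 (0.909 to 1.13). With 9375 and 17231 cytosines, Mt_3 and Mt_4 held nearly all of the mitochondrial cytosines, so the pooled value rests on them. The plastid sequence had 0.796 (0.588 to 1.11) from 1813 cytosines, an interval that included both the nuclear and the mitochondrial values.

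**Figure D3:**
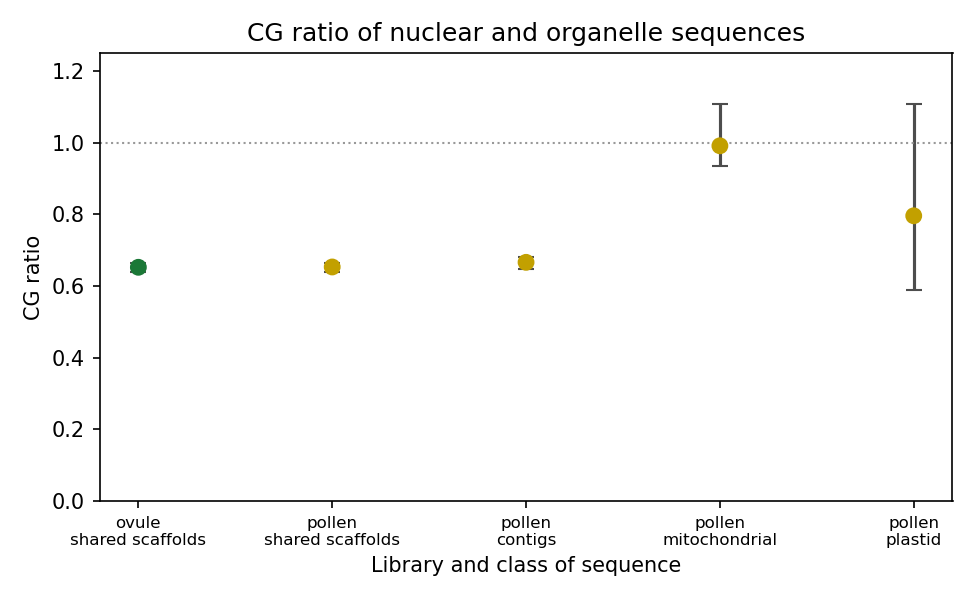
CG ratio (vertical axis, no unit) of the 22 shared scaffolds in ovule and pollen and of contigs, mitochondrial and plastid sequences in pollen (horizontal axis), where points are pooled values, bars are 95% intervals from resampling blocks and the dotted line marks 1. Nuclear sequences lie at 0.652 to 0.666 and mitochondrial sequences at 0.991.

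The plastid and mitochondrial lists of pollen also differed in how often both strands of a CG were listed. This share was read as how fully a sequence was covered, a reading that was not tested. Of the listed CG cytosines, 77.0% in mitochondrial sequences had the cytosine of the opposite strand listed too (Wilson 95% interval 75.8% to 78.2%), compared with 70.5% on the shared scaffolds (70.4% to 70.6%). Mt_4 reached 86.9% (85.6% to 88.0%) and Mt_3 62.6% (60.4% to 64.8%). In the plastid it was 12 of 258 CG cytosines, or 4.65% (2.68% to 7.95%). Why it was so low there was not tested, and the reading as coverage does not explain it. The ovule library had 69.1% on the shared scaffolds, and no organelle sequence of the ovule was analysed here. These intervals cover counting error only and treat cytosines as independent.

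The CG ratio varied widely between genic blocks. Over 518 blocks with at least 300 cytosines in each library, the median was 0.620 in ovule and 0.631 in pollen. The central 90% ran from 0.310 to 0.924 in ovule and from 0.309 to 0.937 in pollen. The ratio was below 1 in 500 blocks in ovule and in 501 in pollen. The 2 libraries share the reference sequence and most of these cytosines, so like values in both are expected. Ranked by the mean of both libraries, the lowest ratios were found at 8456526 to 8460643 of scaffold_8568, with 0.178 in ovule (0.0955 to 0.264) and 0.126 in pollen (0.0465 to 0.211), and at 6172553 to 6176402 of the same scaffold, with 0.171 (0.109 to 0.246) and 0.150 (0.0956 to 0.216). The highest were found in the block of scaffold_9393 at 8798366 to 8804610, with 1.699 in ovule (1.36 to 2.03) and 1.59 in pollen (1.37 to 1.83), and at 6420136 to 6422611 of scaffold_9227. The latter had 1.701 and 1.502, with intervals of 0.349 to 2.16 and 0.123 to 2.18 that reached far below 1. In pollen alone the highest block was another, at 7596049 to 7599078 of scaffold_9647_1, with 1.617 in pollen and 1.517 in ovule. By scaffold, the pollen ratio ran from 0.437 on scaffold_9959 to 0.817 on scaffold_9440.

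Within blocks, the CG ratio was higher at the edges than 2000 to 4000 bp inside. In 327 blocks of at least 8000 bp, the ratio within 200 bp of an edge was 0.706 in ovule (0.666 to 0.749) and 0.687 in pollen (0.645 to 0.729). Between 2000 and 4000 bp from the edge it was 0.548 (0.519 to 0.577) and 0.552 (0.522 to 0.584). The difference was 0.158 in ovule (0.111 to 0.212) and 0.135 in pollen (0.0848 to 0.189). In the 97 blocks of at least 64000 bp alone, the lowest ratios lay nearer the edge and the ratio rose again deeper inside. The edge value there was 0.691 in ovule and 0.658 in pollen. At 800 to 1000 bp, a distance chosen after the values were seen, it was 0.551 and 0.548, lower than at the edge by 0.140 in ovule (0.0399 to 0.234) and 0.110 in pollen (0.0196 to 0.201). Of 10 inner distances, the edge exceeded 3 in ovule and 1 in pollen with an interval above 0. Against 2000 to 4000 bp the difference was not separated from 0, at 0.0587 in ovule (-0.0484 to 0.163) and 0.0306 in pollen (-0.0731 to 0.133). In these same blocks the ratio at 16000 to 32000 bp exceeded that at 2000 to 4000 bp by 0.0430 in ovule (-0.0260 to 0.107) and 0.0461 in pollen (-0.0297 to 0.116), which does not resolve a rise. Against 800 to 1000 bp the excess at 16000 to 32000 bp was 0.124 in ovule (0.0472 to 0.193) and 0.126 in pollen (0.0468 to 0.193). It was above 0 in both libraries at each distance between 600 and 2000 bp and at 4000 to 8000 bp. The edge difference was smaller, 0.073 in ovule and 0.074 in pollen, where blocks were ended by gaps of over 500 bp, and larger, 0.249 and 0.243, where they were ended by gaps of over 5000 bp. Which block edges are gene ends was not known, and neither was the strand of the genes.

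**Figure D4:**
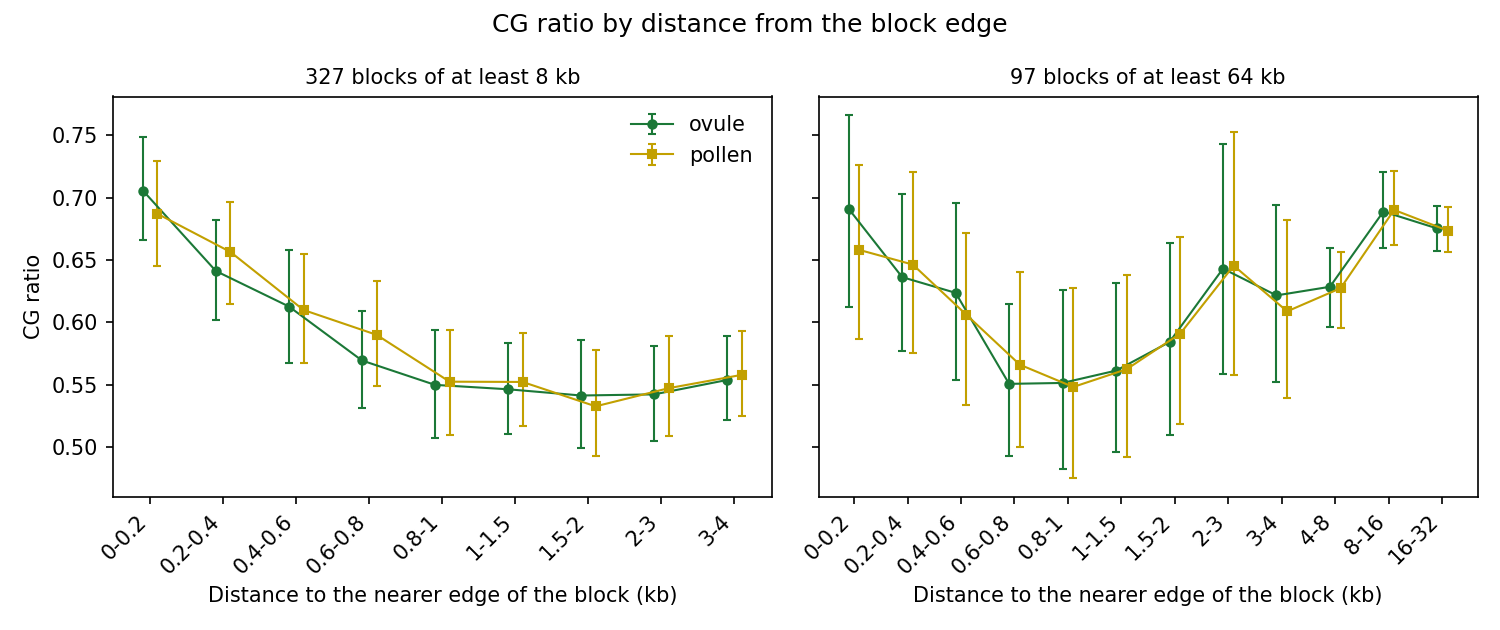
CG ratio (vertical axis, no unit, not starting at 0) by distance in kb to the nearer edge of the block (horizontal axis) in ovule and pollen, in 327 blocks of at least 8000 bp (left) and in the 97 of them of at least 64000 bp (right), with 95% intervals from resampling blocks. All blocks of a panel are long enough for each of its distances, but not each had cytosines listed at every distance (319 to 327 blocks on the left and 93 to 97 on the right). In the left panel the ratio falls from 0.706 in ovule and 0.687 in pollen at the edge to about 0.55 between 2000 and 4000 bp.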

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

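All alternatives here were chosen after seeing the data. None of the alternatives fixed beforehand was run, since each changes a methylation level, a coverage minimum or a gene, which the lists do not hold. Of 84 alternative values over 13 results, 55 stayed within the 95% interval of the reported value, or within 1.5 times a count, 28 did not and 1 reversed its direction. Most of the 55 came from leaving out 1 scaffold, which keeps most cytosines, so the count is little support. For instance, scaffold_690 held 37170 of the 4246429 ovule cytosines. For CHH, all sequences in both lists were the same 22 scaffolds, so that value could not differ. The edge minus interior difference in CG ratio was 0.0734 in ovule and 0.0736 in pollen with block gaps of 500 bp, and 0.249 and 0.243 with 5000 bp. With only the 97 blocks of at least 64000 bp it was 0.0587 and 0.0306, with intervals that include 0. In these blocks the edge was also set against 10 inner distances in place of 2000 to 4000 bp. At 600 to 1500 bp the difference stayed within the interval. At 200 to 400, 400 to 600, 1500 to 2000, 2000 to 3000, 3000 to 4000, 4000 to 8000 and 8000 to 16000 bp it was smaller, in ovule 0.0548, 0.0674, 0.107, 0.0480, 0.0695, 0.0626 and 0.00217. In pollen it was 0.0118, 0.0520, 0.0672, 0.0126, 0.0493 and 0.0307 at the first 6 of these distances, and -0.0321 at 8000 to 16000 bp, with an interval of -0.111 to 0.0437. The median CG ratio over blocks was 0.620 in ovule and 0.631 in pollen, below the pooled values, which weight long blocks more. Blocks at least 1.5-fold higher in pollen numbered 24 with gaps of 500 bp, 9 with 5000 bp, 42 with a minimum of 100 cytosines and 2 with a minimum of 1000. Blocks at least 1.5-fold lower in pollen numbered 6 with gaps of 5000 bp, 33 with a minimum of 100 and 1 with a minimum of 1000. The cause of these changes was not tested, beyond fewer blocks being counted under a higher minimum. Unknown depth leaves open how many reads lie behind a listed cytosine.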

Other observations

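The tests of CG recovery, of mitochondrial sequences and of blocks of like size were chosen after the result they bear on was seen. Block length went with the CG ratio, with the lowest values in blocks of middle length. In pollen, 347 blocks under 2000 bp had a pooled CG ratio of 0.777 (95% interval 0.742 to 0.811), 164 blocks of 2000 to 8000 bp 0.587 (0.542 to 0.635) and 150 blocks of 8000 to 32000 bp 0.571 (0.544 to 0.596). The 142 blocks of 32000 to 128000 bp had 0.647 (0.632 to 0.663), and 35 longer blocks, with 35.0% of the cytosines, had 0.693 (0.672 to 0.711). In ovule the values were 0.774, 0.567, 0.569, 0.647 and 0.694 in the same order. In windows of 1000 bp, the CG share of listed cytosines in pollen ran from 3.14% at the 5th percentile over a median of 10.6% to 24.3% at the 95th percentile.

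CG cytosines were under-represented in nuclear genic sequence, at 0.652 in ovule and 0.653 in pollen of the level set by CHG. A ratio that falls below 1 in any sequence listed this way is argued against by the mitochondrial value of 0.991 (0.934 to 1.11) in pollen. That value rests almost wholly on Mt_3 and Mt_4, and on the pollen library alone. CG cytosines missed at random in each library are argued against as the whole cause. The share of ovule CG cytosines listed in pollen was 1.046 times (1.043 to 1.049) that of CHH cytosines of the same 1000-bp windows, 82.2% against 78.6%, where the deficit would need at most 0.653 times. In the other direction it was 1.052 times (1.049 to 1.056). CG cytosines of nuclear sequence missed in both libraries alike stay open, since they are not seen without the genome sequence. Loss of methylated CG over evolutionary time may contribute and stays an untested hypothesis, since it needs the TG and CA dinucleotides and methylation levels. Differences in base order between nuclear and mitochondrial genes stay open too.

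The CG ratio was higher at block edges than 2000 to 4000 bp inside in 327 blocks of at least 8000 bp, while in the 97 of at least 64000 bp the lowest values lay nearer the edge. Base composition stays open as a cause. With 400-bp pieces matched on CHG share in 10 classes, 72.1% of the difference in CG share remained (63.9% to 79.2%), 2.92 of 4.05 percentage points. The rule set beforehand against this cause was met, since most of the difference remained with an interval above 0. If the CG ratio did not vary with CHG share, 58.7% would remain, and the interval lies above that. However, the CHG share of a 400-bp piece rests on few cytosines, so matching on it can leave part of its effect in place. The 58.7% was also given no interval. Matching thus does not decide whether CHG share is the whole cause. Other features of base composition were not matched. In a comparison chosen after the values were seen, the ratio was higher at the edge than 400 to 1000 bp inside by 0.128 in ovule (0.0812 to 0.174) and 0.102 in pollen (0.0542 to 0.1505). The CHG share of the cytosines outside CG differed, edge minus inside, by -0.8189 percentage points in ovule (-1.71 to 0.0209) and by -0.9957 in pollen (-1.89 to -0.189). A higher CHG share at the edges was not excluded by the rule set for it, because the ovule interval reached 0. Still, the CHG share was not seen to be higher at the edge in either library, while the CG ratio was. This argues against a higher CHG share as the cause, for this contrast alone. The CHG share is the divisor of the CG ratio, so a lower CHG share at the edge raises the ratio by itself. How much of this contrast comes from the divisor was not computed. The share of CG among listed cytosines was also higher at the edge than in each distance class between 400 and 1000 bp, in both libraries. At 2000 to 3000 bp the CHG share did lie below that at the edge, 17.5% against 20.05% in ovule and 17.5% against 19.8% in pollen. Whether any end of read coverage gives a high ratio cannot be told apart from a property of the edges of genes. Within 200 bp of 2025 gaps of 200 to 1000 bp inside blocks, the pollen ratio was 0.641 (0.615 to 0.664), below the edge value of 0.687, above the value of 0.552 at 2000 to 4000 bp and close to the 0.653 of all shared scaffolds. It was no higher than the 0.656 at 8000 to 16000 bp, so a raised ratio at gaps is not shown. That value comes from the 254 blocks with cytosines listed at this distance, the longer of the 327. The gaps lay in 277 blocks, so the sets of blocks are not the same. A gene annotation would settle it. No biological explanation was tested.

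The block of scaffold_9393 with 2.11 times as many cytosines in pollen as in ovule held stretches made almost only of C and G. In the 500-bp window at 8800001 to 8800500, 496 positions were listed as cytosines of either strand. The longest run of adjacent CHH positions in ovule, 72 bp, lay at 8822120 to 8822191 of the same scaffold, and that in pollen, 81 bp, at 9725801 to 9725881 of contig_9986. The ovule CHH list held 22 scaffolds and no contigs, against 63 sequences in pollen, so these 2 runs are not comparable. On the 22 shared scaffolds, only 3 windows had at least 70% of their positions listed, all on scaffold_9393 and all higher in pollen. The contigs listed in pollen were not searched for such windows. Better coverage of very C-rich sequence by the pollen library could not be judged from the 1 such window outside the block, at 8822501 to 8823000, with a log2 ratio of 1.49. That window lay near the block on the same scaffold, so it may not be independent of the block. In the 31 windows with 60% to 70% listed, the pollen to ovule ratio was 1.028, and in 1671 windows with 50% to 60% it was 1.0203. Patchy coverage stays open as well. Of 156 other blocks of like size, 0 differed by as much (exact upper limit 2.34%, largest absolute log2 ratio 0.588). The block had been picked for its high ratio, so that outcome was all but fixed for blocks higher in pollen. The upper limit holds only for a block chosen beforehand, and the count decides nothing. Whether such sequence lies in the genome or arose in its assembly was not tested, and no biological explanation was tested.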
